A study of Homo sapiens with 6 samples.

How the data were processed

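Gene expression was measured in SH-SY5Y cells, an established human neuroblastoma line, with Affymetrix whole-transcript arrays of 1 colour (biotin label). Per the labels' protocols, the cells were differentiated with atRA (retinoic acid) over 96 h, a bioactive compound was given at 15 µM, and labelled cDNA was prepared from 100 ng of total RNA. The 6 arrays form 2 groups of 3, labelled 15EN and VC, where the labels spell out VC as vehicle control and leave 15EN unexpanded. The series title names eurycomanone as the compound studied. The labels give each replicate number its own passage (33, 34 and 35 in titles and source names) in both groups, while every description names passage 33. Nothing else in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

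The values analysed are the log2 signals the authors deposited, 1 per probe set and array. Per the submitters' processing notes they were made with the Transcriptome Analysis Console, and its version, the summarization and normalization method and the genome build are not given in the sources used here. The scale was judged from the values, which run from 2.20 to 18.8 with array medians of 7.67 to 7.76. The table holds 24351 probe sets, of which 2903 are controls. Of the 21448 gene probe sets, 17709 carry 1 gene symbol in the platform annotation, 0 carry several and 3739 are unnamed here. All 17709 Entrez identifiers matched a RefSeq gene table (assembly GRCh38.p14), and 0 symbols changed on update. Where a gene had more than 1 probe set, the one with the highest mean over the 6 arrays was kept (22 set aside), which left 17687 genes. No filter on dim probe sets was applied. The values carry no detection calls, so the 90th percentile of the 612 negative control probe sets (7.41 to 7.99 per array) is used only to describe a gene as dim. Medians over genes were 7.60 to 7.72 per array, and medians of the negative controls 4.75 to 5.06. Dim thus covers a large part of all genes and does not mean undetected. The number of arrays limits the precision.

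Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, group as the only term, two-sided), with Benjamini-Hochberg adjustment over the 17687 genes and a threshold of adjusted p 0.05. Errors beside log2 differences are standard errors of that fit, errors beside group means are SDs over 3 arrays, and every adjusted p of a gene comes from limma. Genes of at least 2-fold at an unadjusted p under 0.05 were counted as a description. The 36 gene lists were written from textbook knowledge, and 1027 of their 1183 distinct genes were measured. Each list with at least 5 measured members was compared with all other genes by camera in limma (preset correlation 0.01, adjusted over the lists), and again with the correlation estimated for each list. The fry test was run as a self-contained alternative. Members past the threshold were counted over all genes and adjusted over the list alone. The lists of other cell types covered substrate-adherent neuroblastoma cells, fibroblasts with extracellular matrix, and Schwann cells with other glia.

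Genes named in the text follow a rule. It takes up to 12 genes per direction of largest change among those past the threshold with the same direction in all 3 same-numbered differences. It adds up to 4 members of smallest p for each called list and for the 5 lists on dopamine, GABA and synaptic vesicles, up to 2 members for each list of other cells, and a fixed set of dopamine and GABA genes. The samples, the tests, the lists, this rule and most alternatives were fixed before the data were examined. Exceptions are named where they occur.

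Same-numbered arrays deviated together from their group means. Across genes, the correlations of these deviations were 0.229, 0.162 and 0.133 for replicates 1, 2 and 3, against -0.138 to -0.0165 for arrays of different numbers. The labels also tie each number to a shared passage, so the numbers were taken to pair the samples, and the fit with the replicate number as a block was run as an alternative. Other alternatives were quantile normalization, median centring, a filter that left out the dimmest tercile of probe sets, each array or both arrays of a number left out, array weights, the mean of a gene's probe sets, all gene probe sets, a trended robust prior, and a least squares fit without moderation. Scaling by the hybridization controls and removal of a brightness trend by loess were added after the data were seen.

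The procedure was tested on simulated data with 17687 genes, 3 arrays per group and 200 changed genes in each of 20 simulations. It recovered 0.3% of genes changed by 0.5 on the log2 scale, 14.3% at 1, 62.9% at 1.5 and 91.9% at 2, and 4.29% of its calls were false. In the data 3787 genes passed, which makes the adjusted threshold less strict there than with 200 changed genes. The recovered shares are therefore no estimate of what was missed in the data. A list shifted by 0.5 was called in 20 of 20 simulations, with 0 other lists called. The simulated genes were independent of each other, so false list calls from correlated members could not arise. In the data the estimated correlation within a called list reached 0.607 (histones). Plots were drawn with matplotlib 3.10.9. No array was left out and 0 columns of values were unused. Gene coordinates are not given, since the build of the array annotation is not named in the sources used here.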

Results

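SH-SY5Y is a human neuroblastoma line of sympathetic lineage that takes on neuron-like features under retinoic acid. Whole-transcript arrays were run on 3 samples labelled 15EN and 3 vehicle controls (VC), with 1 sample of each group at each of 3 passages. The treatment text gives 15 µM of the bioactive compound, and the series title names eurycomanone, a compound of Eurycoma longifolia root. Median log2 signal was 7.74, 7.76 and 7.67 in 15EN replicates 1, 2 and 3, and 7.73, 7.72 and 7.69 in the VC replicates. Over all probe sets, the VC arrays correlated with each other at Pearson's r of 0.990 to 0.992. In the 15EN group, replicates 1 and 2 correlated at 0.992, and replicate 3 with these at 0.979 and 0.980. Arrays of different groups correlated at 0.966 to 0.973. No 2 arrays held the same values. The first principal component (64.2% of the variance) separated the groups, with 15EN replicate 3 at -25.2, 15EN replicates 1 and 2 at -61.1 and -61.9, and the VC arrays at 48.4 to 50.4. The next component (17.1%) set 15EN replicate 3 at -56.7 apart from the 5 other arrays.

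The 15EN and VC arrays were compared to ask which transcripts differ with the compound, and whether those of dopamine and GABA signalling, named in the series title, are among them. The largest rise was in HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1. Its log2 signal was 14.29 ± 0.65 in 15EN and 6.49 ± 0.34 in VC (SD, n = 3), a difference of 7.80 ± 0.33 (SE, adjusted p = 4.36e-06). The VC level lay within the range of the negative controls, below their 90th percentile and above their medians in the VC arrays (4.97 to 5.06). The size of this rise is therefore uncertain. The stress and growth-arrest genes ATF3 (4.32), GDF15 (4.27) and GADD45A (3.43), the immediate-early genes IER3 (4.85) and FOSL1 (3.81), the transcription factor KLF5 (4.54) and the clock repressor NR1D1 (4.15) also rose, all as log2 differences. ABCG1, a sterol exporter (4.12), the TNF receptor family member EDA2R (3.74), DHRS2 (3.63) and PIK3R1, a regulatory subunit of PI3-kinase (3.35), completed the 12 genes of largest rise, with adjusted p from 4.36e-06 to 0.00123. Among the 12 genes of largest fall were the small GTPase RAB7B (-5.43), the chemokine CCL2 (-5.27), SCARA3 (-5.23) and the receptor tyrosine kinase KIT (-5.18 ± 0.36, adjusted p = 6.44e-05). KIT went from 15.47 ± 0.17 in VC to 10.29 ± 0.81 in 15EN. Complement C7 (-4.56), the kinases MAP2K6 (-4.48) and MAP3K8 (-3.71), the matrix proteins ABI3BP (-4.33) and elastin, ELN (-3.77), LRRC17 (-4.11), the protocadherin PCDHB6 (-3.71) and the calcium channel subunit CACNG4 (-3.69) fell as well. CCL2 was the most variable of these, at 4.56, 7.09 and 9.94 in 15EN replicates 1, 2 and 3 against 12.46 ± 0.56 in VC. The means of IER3, KLF5, ATF3, ABCG1 and DHRS2 in VC, and of RAB7B, CCL2, SCARA3, MAP2K6 and MAP3K8 in 15EN, also lay within the range of the negative controls. CCL2 in 15EN replicate 3 (9.94) lay above that range. The sizes and the order of all these differences are thus uncertain. The fall of ELN no longer passed without VC replicate 2 (adjusted p = 0.0612) or VC replicate 3 (0.057).

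In all, 3787 of 17687 genes (21.4%) passed adjusted p 0.05, 2179 higher and 1608 lower in 15EN, and 3779 of them had the same sign in all 3 same-numbered differences. At least 2-fold at an unadjusted p under 0.05 were 1501 higher and 1140 lower genes, and 5697 genes had such a p. Directions are relative to the median gene, whose difference was 0.01 as deposited. When arrays were scaled to equal hybridization controls, which were dimmer in 15EN, every difference rose by 0.87 and that median to 0.88. Values after this scaling are therefore to be read against 0.88. The test there is still against 0, so each fall shrinks by the added constant and the smaller falls lose their call. Their distance from the median gene stays the same. The split of calls went from 2179 higher and 1608 lower (57.5% higher) to 12150 higher and 437 lower (96.5%), with 0 genes called in opposite directions. After removal of a brightness trend the split was 1892 higher and 1895 lower (49.96% higher), and after quantile normalization 2036 and 1786 (53.3%). Leaving out 1 array gave lower counts, in a smaller fit, for each array except 15EN replicate 3, and 0 genes changed direction. Without VC replicate 1 there were 1424 higher and 1122 lower genes, without VC replicate 2 1301 and 970, and without VC replicate 3 1378 and 1062. Without 15EN replicate 1 or 2 they were 1498 and 1139 or 1472 and 1213, and without 15EN replicate 3, 3227 and 2240.

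**Figure D1:**
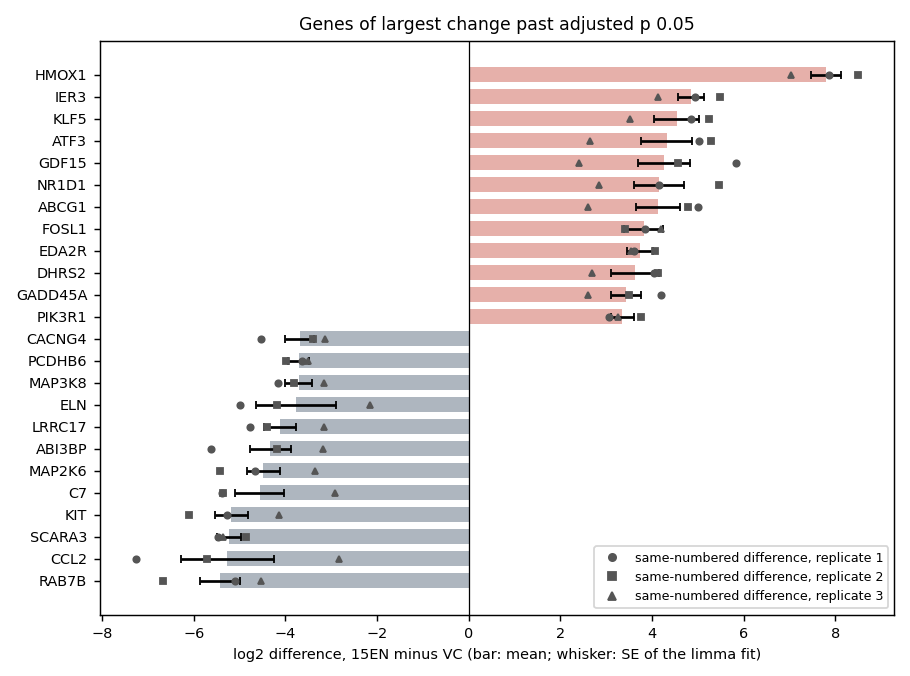
Log2 differences, 15EN minus VC, of the 12 genes of largest rise and the 12 of largest fall past adjusted p 0.05 (bars are means, whiskers are SEs of the limma fit, points are the 3 same-numbered differences). HMOX1 reaches 7.80 and CCL2 has the widest whisker (SE 1.01). Both rest on a group whose mean lies within the range of the negative controls, although CCL2 in 15EN replicate 3 (9.94) lies above that range.

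Of the 36 gene lists, 11 differed from other genes by camera with the preset correlation, and 0 of the 11 did so with an estimated correlation. That setting leaves far fewer degrees of freedom, so a call lost there does not show that a list did not differ. Targets of the tumour suppressor p53, which act in growth arrest, DNA repair and apoptosis, rose together. Of 27 measured targets, 23 were higher and 0 lower, the same 23 when adjusted over the list alone, with a median log2 difference of 2.07 (camera adjusted p = 5.74e-14, and adjusted p = 0.326 with an estimated correlation). Besides EDA2R and GADD45A these included the nuclease gene AEN (3.17 ± 0.26, adjusted p = 0.000147) and TIGAR, a regulator of glycolysis (2.86 ± 0.26, adjusted p = 0.00019). Ribosome biogenesis factors rose with a median of 1.14, 21 higher and 0 lower of 31 (23 higher adjusted over the list alone; camera adjusted p = 1.11e-09, and adjusted p = 0.326 with an estimated correlation). RRP1 rose by 2.07 ± 0.19, UTP4 by 1.98 ± 0.21, UTP14A by 2.38 ± 0.27 and RRS1 by 1.62 ± 0.20, all of them proteins of rRNA processing and subunit assembly. Immediate-early genes, which respond rapidly to stimulation, had a median of 1.04, with 14 higher and 1 lower of 31 (17 and 1 adjusted over the list alone; camera adjusted p = 2.5e-07, and adjusted p = 0.68 with an estimated correlation). IER2 rose by 2.76 ± 0.26 and IER5 by 1.97 ± 0.22 beside IER3 and FOSL1. Without 15EN replicate 3 the count of higher members was 23. Replication-dependent histone genes had a median of 0.67, with 15 higher and 0 lower of 47 (23 and 2 adjusted over the list alone; camera adjusted p = 8.16e-07, and adjusted p = 0.68 with an estimated correlation). H1-4 rose by 1.44 ± 0.23, H4C8 by 1.49 ± 0.26, H2BC12 by 1.05 ± 0.21 and H3C11 by 1.32 ± 0.26. These values are uncertain per gene because genes within a histone class closely resemble each other. The histone count was 9 without 15EN replicate 1 or without VC replicate 1, 10 without 15EN replicate 2, and 30 without 15EN replicate 3. Nuclear genes of oxidative phosphorylation had a median of 0.38, with 10 higher and 2 lower of 64, also when adjusted over the list alone (camera adjusted p = 0.00674, and adjusted p = 0.68 with an estimated correlation). The ATP synthase subunits ATP5MC1 (1.36 ± 0.23) and ATP5F1D (1.09 ± 0.25) and the complex I subunit NDUFA6 (1.52 ± 0.30) rose, whereas the cytochrome c oxidase subunit COX4I1 fell (-1.09 ± 0.23, and -0.22 without passing after scaling to the hybridization controls). ATP5F1D was dim in both groups and lost its call without VC replicate 2 (adjusted p = 0.0614). The call of this list was lost after quantile normalization (median 0.29, adjusted p = 0.0537), without dim genes (median 0.38, adjusted p = 0.0637) and after removal of a brightness trend (median 0.24, adjusted p = 0.0825). Its count of higher members ran from 2 without VC replicate 2 to 19 without 15EN replicate 3. It was 3, 5, 6 and 3 without 15EN replicates 1 and 2 and VC replicates 1 and 3.

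**Figure D2:**
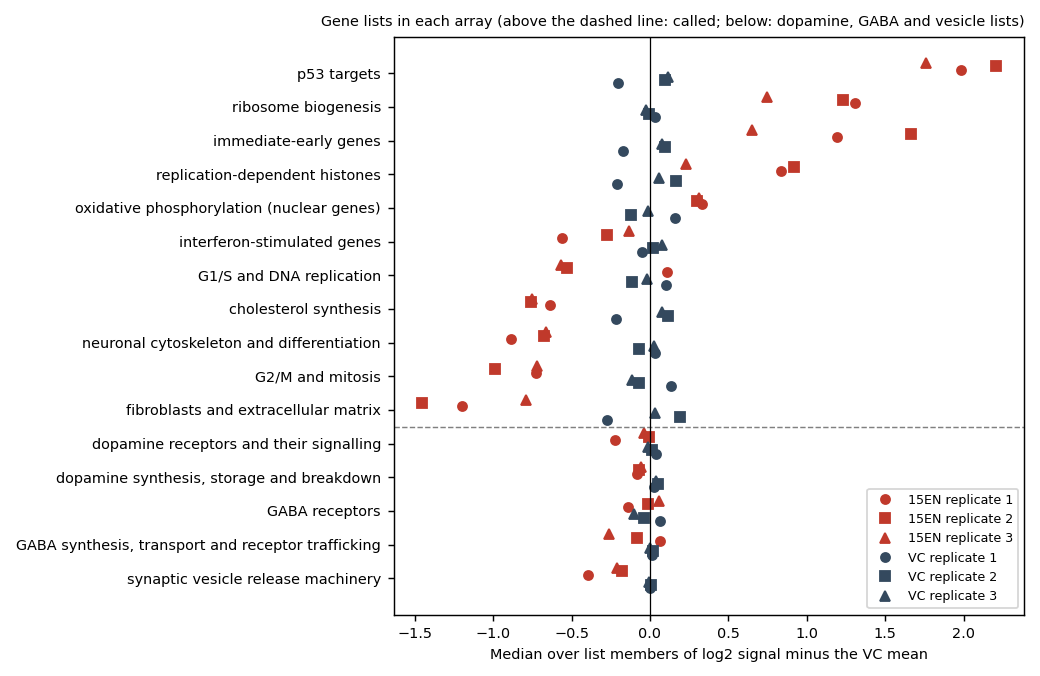
Median over the measured members of each list of log2 signal minus the VC mean, 1 point per array. The 11 lists above the dashed line differed from other genes by camera, and for p53 targets the 15EN arrays lie at 1.76 to 2.21 and the VC arrays at -0.20 to 0.12. The values are as deposited, and of the 6 lists that fell the medians of all except the fibroblast and matrix list turn positive when arrays are scaled to the hybridization controls.

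Genes of the neuronal cytoskeleton and of neuronal differentiation fell. Of 35 measured, 0 were higher and 16 lower (1 and 18 adjusted over the list alone), with a median of -0.67 as deposited and 0.20 after scaling to the hybridization controls (camera adjusted p = 8.16e-07, and adjusted p = 0.238 with an estimated correlation). The log2 differences were -2.69 ± 0.25 for the neurofilament gene NEFM, -2.51 ± 0.29 for the β-tubulin gene TUBB2B, -1.72 ± 0.22 for STMN2, a microtubule regulator of growing neurites, and -1.47 ± 0.20 for the neuronal RNA-binding protein gene ELAVL3 (adjusted p from 0.00019 to 0.00099). Genes of G2/M and mitosis fell with a median of -0.74 (0.13 after scaling to the hybridization controls), with 0 higher and 19 lower of 39 (24 lower adjusted over the list alone; camera adjusted p = 8.07e-11, and adjusted p = 0.326 with an estimated correlation). Examples were the mitotic kinesin KIF20A (-2.40 ± 0.25), the centromeric histone CENPA (-1.69 ± 0.23), DLGAP5 (-1.57 ± 0.23) and topoisomerase TOP2A (-1.37 ± 0.21). Genes of G1/S and DNA replication had a median of -0.29 (0.58 after that scaling), with 1 higher and 8 lower of 38 (1 and 12 adjusted over the list alone; camera adjusted p = 0.00401, and adjusted p = 0.743 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 1.84 ± 0.30, UHRF1 by 1.37 ± 0.29, CHAF1A by 1.08 ± 0.21 and the histone mRNA-binding protein gene SLBP by 1.07 ± 0.23. The list median in 15EN replicate 1 was 0.11, close to the 0.10 of VC replicate 1. The call was lost without 15EN replicate 3 (median -0.21, adjusted p = 0.125) and with array weights (median -0.22, adjusted p = 0.103). Its count of lower members was 12 without 15EN replicate 1 and 5 without VC replicate 2 or 3. After scaling to the hybridization controls, CHAF1A (-0.21), SLBP (-0.20), UHRF1 (-0.51) and TOP2A (-0.50) no longer passed against 0, with the constant added to every gene.

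Fibroblast and extracellular matrix genes fell with a median of -1.07 (-0.20 after scaling to the hybridization controls), 0 higher and 13 lower of 23 (1 and 13 adjusted over the list alone; camera adjusted p = 1.26e-06, and adjusted p = 0.68 with an estimated correlation). The collagen genes COL4A1 (-3.57 ± 0.29), COL5A1 (-2.64 ± 0.30) and COL6A1 (-1.93 ± 0.31) fell, as did TIMP3, an inhibitor of matrix metalloproteinases (-2.17 ± 0.31). The list median relative to the VC mean was -1.20, -1.45 and -0.79 in 15EN replicates 1, 2 and 3. Markers of substrate-adherent neuroblastoma cells moved in both directions, with 5 higher and 4 lower of 31 (5 and 4 adjusted over the list alone), a median of 0.09 and camera adjusted p = 0.847. Their higher count was 3 without 15EN replicate 2 or VC replicate 3, and without 15EN replicate 3 there were 4 higher and 6 lower. Among them FOSL1, also an immediate-early gene, and YAP1 (1.43 ± 0.21) rose. Markers of Schwann cells and other glia had 0 higher and 0 lower of 17 (also 0 and 0 adjusted over the list alone), a median of -0.08 and camera adjusted p = 0.945. Of these, GFRA3 differed by 0.65 ± 0.22 (adjusted p = 0.0569) and NGFR by -0.64 ± 0.27 (adjusted p = 0.125). GFRA3, dim in both groups, passed after quantile normalization (adjusted p = 0.0336), after removal of a brightness trend (0.0358) and after scaling to the hybridization controls (0.000443), and NGFR after removal of a brightness trend (0.0443). Cholesterol synthesis genes fell with a median of -0.55 (0.32 after scaling to the hybridization controls), 0 higher and 9 lower of 20 (3 and 9 adjusted over the list alone; camera adjusted p = 0.000205, and adjusted p = 0.326 with an estimated correlation). The pathway enzymes DHCR7 (-3.22 ± 0.21), MSMO1 (-2.45 ± 0.34) and SQLE (-1.81 ± 0.27) and the sterol sensor INSIG1 (-2.55 ± 0.23) fell. Without 15EN replicate 3 the cholesterol list had 3 higher and 11 lower members. Interferon-stimulated genes had a median of -0.26 (0.61 after that scaling), with 0 higher and 5 lower of 28 (3 lower adjusted over the list alone; camera adjusted p = 0.00986, and adjusted p = 0.68 with an estimated correlation). IRF9, a subunit of the interferon-responsive complex ISGF3, fell by 1.21 ± 0.22, and OAS3 (-0.99 ± 0.20), IFI44 (-0.85 ± 0.22) and OAS1 (-0.73 ± 0.22) fell while dim in both groups. IFI44 failed the threshold without 15EN replicate 1 or 2 or VC replicate 2 or 3 (adjusted p = 0.0552 to 0.0861). OAS1 failed it without any of 5 arrays (0.0639 to 0.161), 15EN replicate 3 being the exception. After scaling to the hybridization controls IRF9 (-0.34), OAS3 (-0.12), IFI44 (0.02) and OAS1 (0.14) did not pass against 0, with the constant added to every gene. The call of the interferon list was lost without dim genes (median -0.32, adjusted p = 0.0981), without 15EN replicate 1 (median -0.13, adjusted p = 0.0502) and after that scaling (0.0967). Its count of lower members was 9 without 15EN replicate 3 and 2 or 3 without any other array.

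Dopamine genes showed falls in a few enzymes. Of 21 measured genes of dopamine synthesis, storage and breakdown, 0 were higher and 3 lower, also when adjusted over the list alone, and the list did not differ from other genes by camera (median -0.09, adjusted p = 0.463). By fry, which asks whether the list itself changed, it was lower (adjusted p = 0.00509). With the replicate number as a block, which leaves fewer degrees of freedom, fry called 0 lists (lowest adjusted p = 0.0647). DDC, the decarboxylase that makes dopamine from L-DOPA, fell by 2.29 ± 0.26 (5.39 ± 0.39 in 15EN, 7.69 ± 0.26 in VC, adjusted p = 0.000359), at levels within the range of the negative controls in both groups. DBH, which converts dopamine to noradrenaline, fell by 1.59 ± 0.23 (adjusted p = 0.00112) to a dim level in 15EN, and the aldehyde dehydrogenase ALDH2 by 1.22 ± 0.24 (adjusted p = 0.00553). TH, the rate-limiting enzyme of dopamine synthesis, was dim in both groups and differed by -0.09 ± 0.21 (adjusted p = 0.818). The vesicular transporter SLC18A2 differed by -0.02 ± 0.23 (adjusted p = 0.969) and the dopamine transporter SLC6A3 by -0.44 ± 0.21 (adjusted p = 0.192), both also dim. PNMT, the adrenaline-forming enzyme, was dim in both groups and missed the threshold at 0.75 ± 0.25 (adjusted p = 0.0544). It passed with the replicate number as a block (0.0484), without 15EN replicate 2 (0.0471), after quantile normalization (0.0336), without dim genes (0.0419) and after removal of a brightness trend (0.0329). Of 27 dopamine receptor and signalling genes, 1 was higher and 5 lower (2 and 6 adjusted over the list alone). That list had a positive median (0.07) but a negative mean (-0.21) and test direction (camera adjusted p = 0.407). The adenylyl cyclase ADCY1 fell by 2.69 ± 0.25 (adjusted p = 0.000197) to a dim level in 15EN, and the G protein subunits GNAI2 by 1.64 ± 0.27, GNAO1 by 1.09 ± 0.21 and GNAS by 0.88 ± 0.22. GNAS lost its call without VC replicate 1 (adjusted p = 0.0607) or VC replicate 3 (0.0706), and the list's count of lower members was 3 without either. The list's higher count was 0 without 15EN replicate 1 or 2 or VC replicate 1 or 2. Without 15EN replicate 3 the list had 2 higher and 7 lower members. After scaling to the hybridization controls, which adds a constant to every gene, the falls of ALDH2 (-0.35), GNAO1 (-0.22) and GNAS (-0.01) no longer passed against 0. PNMT then stood at 1.62. TH (0.78) and SLC18A2 (0.85) then lay below the median gene, so their positive values follow from the constant added to every gene and say nothing of these genes.

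GABA genes moved in both directions. Of 28 measured genes of GABA synthesis, transport and receptor trafficking, 6 were higher and 5 lower (7 and 9 adjusted over the list alone), with a median of -0.11 and camera adjusted p = 0.482. GAD1, which makes GABA from glutamate, fell by 1.18 ± 0.25 (9.93 ± 0.27 in 15EN, 11.12 ± 0.38 in VC, adjusted p = 0.00837), and ABAT, which breaks GABA down, by 1.02 ± 0.31 (adjusted p = 0.0386) at dim levels. NLGN2, an adhesion molecule of inhibitory synapses, differed by -1.50 ± 0.26 (adjusted p = 0.00312) and was dim in 15EN. SLC6A6, a taurine transporter, fell by 1.20 ± 0.23 (adjusted p = 0.00465), and PLCL1, which binds a GABA-A receptor-associated protein, rose by 1.89 ± 0.29 (adjusted p = 0.00172). Of 17 GABA receptor genes, 0 were higher and 1 lower, also when adjusted over the list alone (median -0.10, camera adjusted p = 0.675). The gene that fell was GABRA3, a subunit of the GABA-A receptor, at -1.36 ± 0.30 (adjusted p = 0.0101). The GABA-B receptor gene GABBR1, bright in both groups, differed by -0.57 ± 0.29 (adjusted p = 0.215). The dim GABA-A subunit genes differed as well without passing, GABRR2 by 0.68 ± 0.22 (adjusted p = 0.0535) and GABRA4 by 0.55 ± 0.22 (adjusted p = 0.101). GABRR2 passed with the replicate number as a block (adjusted p = 0.0411) and without 15EN replicate 3 (0.0143). ABAT lost its call without 15EN replicate 1 (adjusted p = 0.059) or VC replicate 1 (0.133), 2 (0.0838) or 3 (0.114), and GABRA3 without VC replicate 2 (0.0568). The counts of 6 higher and 5 lower became 2 to 7 and 3 to 9 with 1 array left out. The higher count lay at 2 or 3 without any array except 15EN replicate 3, and the lower count at 3 without VC replicate 1 or 3 and at 9 without 15EN replicate 3. After scaling to the hybridization controls GAD1 (-0.32), ABAT (-0.15), NLGN2 (-0.63), SLC6A6 (-0.33) and GABRA3 (-0.49) no longer passed against 0. GABRR2 (1.55) and GABRA4 (1.42) passed. Both changes come with the constant added to every gene.

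The synaptic vesicle release machinery, proteins that load, dock and fuse vesicles, had a median of -0.28, with 2 higher and 5 lower of 45, also when adjusted over the list alone. It missed the threshold by camera (adjusted p = 0.0535, and adjusted p = 0.418 with an estimated correlation) and was lower by fry without the block (adjusted p = 0.0252). By camera it passed without 15EN replicate 2 (0.0178), without VC replicate 1 (0.0351) and, against a median gene of 0.88, after scaling to the hybridization controls (0.0494, list median 0.59). The active zone protein gene RIMBP2 fell by 2.07 ± 0.23, the vesicle glycoprotein genes SV2A and SV2C by 1.66 ± 0.24 and 1.33 ± 0.21, and the synaptotagmin gene SYT11 by 0.99 ± 0.20 (adjusted p from 0.000355 to 0.00646). After that scaling SV2C (-0.47) and SYT11 (-0.13) no longer passed against 0, with the constant added to every gene. Without 15EN replicate 3 the list had 5 higher and 9 lower members, without 15EN replicate 2 or VC replicate 2 it had 0 higher, and without VC replicate 3 1 higher.

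**Figure D3:**
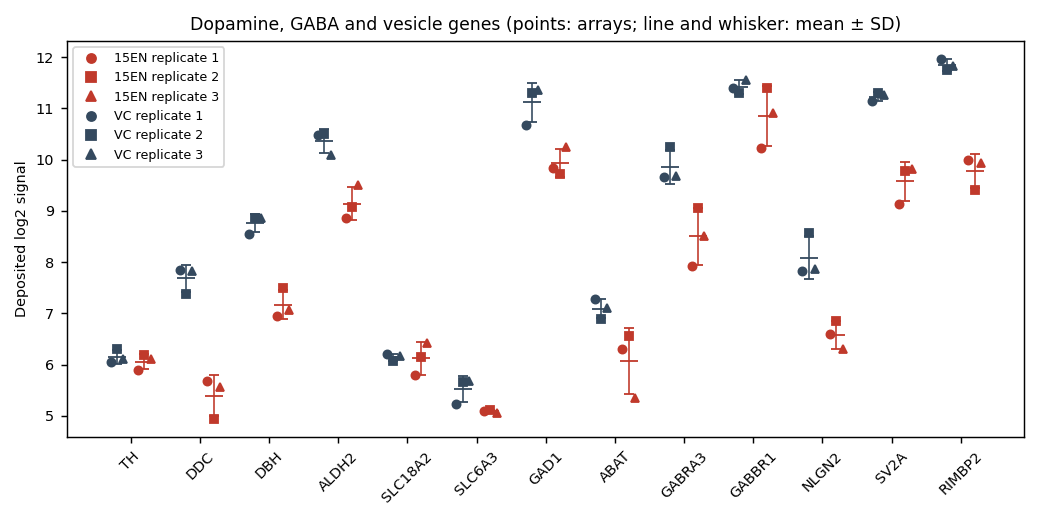
Deposited log2 signal of dopamine, GABA and vesicle genes in each array, with group means and SDs (n = 3). DDC, DBH, GAD1 and RIMBP2 lie lower in every 15EN array than in every VC array, whereas TH and SLC18A2 overlap. After scaling to the hybridization controls DDC, DBH and RIMBP2 still pass as lower, GAD1 does not pass, and TH (0.78) and SLC18A2 (0.85) turn positive while below the median gene (0.88), because the scaling moves all genes alike.

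The other lists did not pass by camera, although several held members that changed. Targets of NRF2, the regulator of antioxidant defence, had 11 higher and 3 lower of 26, also when adjusted over the list alone (camera adjusted p = 0.0715), and passed without 15EN replicate 1 and without VC replicate 3. By fry without the block they were higher (adjusted p = 0.0252). Genes of the unfolded protein and integrated stress response split into 14 higher and 8 lower of 41 (17 and 10 adjusted over the list alone; camera adjusted p = 0.482), and were higher by fry without the block (adjusted p = 0.00833). Retinoic acid response genes had 4 higher and 8 lower of 32 (6 and 9; camera adjusted p = 0.271), apoptosis regulators 9 and 4 of 26 (12 and 4; 0.53), NF-kB and inflammatory genes 7 and 3 of 27 (8 and 4; 0.482), and autophagy and lysosome genes 3 and 8 of 29 (4 and 8; 0.482), where the counts in brackets are adjusted over the list alone and followed by camera's adjusted p. On the same terms heat shock proteins had 3 and 4 of 21 (5 and 5; 0.847), cytosolic ribosomal proteins 1 and 3 of 44 (0 and 1; 0.177, passing after removal of a brightness trend), glycolysis and hypoxia genes 2 and 4 of 30 (2 and 4; 0.482), and chromaffin and dense-core granule proteins 2 and 3 of 20 (2 and 3; 0.482). Adrenergic neuroblastoma regulators had 1 and 4 of 22 (1 and 5; 0.531), sodium and potassium channels 1 and 3 of 27 (1 and 3; 0.407), calcium channels 0 and 2 of 15 (0 and 2; 0.531), and glutamate receptors and transporters 2 and 2 of 34 (1 and 1; 0.663). Cholinergic markers had 2 and 2 of 20 (2 and 2; 0.847), steroid synthesis and receptor genes 1 and 1 of 21 (1 and 1; 0.676), xenobiotic metabolism genes 0 and 0 of 23 (0 and 0; 0.676), and serotonin and opioid genes 0 and 0 of 20 (0 and 0; 0.837). Single arrays moved these counts. The 8 lower retinoic acid genes became 4 without VC replicate 2 or 3 and 5 without VC replicate 1. The 8 lower autophagy genes became 4 without 15EN replicate 1 or VC replicate 2 or 3 and 5 without 15EN replicate 2, and the 3 higher ones 7 without 15EN replicate 3. The 14 higher stress response genes became 9 without 15EN replicate 2, and the 7 higher NF-kB genes 4 without VC replicate 1 or 2. Counts of 4 or fewer in these lists mostly moved by more than 1.5 times as well. Medians and test directions differed in sign for the adrenergic regulators (median 0.03, tested lower), calcium channels (0.01, lower), serotonin and opioid genes (0.00, lower) and cholinergic markers (0.06, lower), and means and test directions for steroid genes (mean 0.00, lower), cholinergic markers (mean 0.01, lower) and glial markers (mean 0.02, lower).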

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

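The comparison of regroupings and the tests of mixed vehicle RNA and of a weaker response were chosen after the result was seen. Probe sets outside the comparison of named genes also differed. Of the 3739 gene probe sets that are unnamed here, 469 (12.5%) passed adjusted p 0.05 in limma, 212 higher and 257 lower in 15EN, and they were set apart because the comparison of genes does not use them. The 4 hybridization control probe sets (bioB, bioC, bioD and cre), which measure spiked transcripts and no gene, were 0.87 higher in VC than in 15EN on the log2 scale (11.30 ± 0.07 against 10.43 ± 0.15, SD, n = 3), with no overlap between the groups. The other controls differed less. The ERCC probe sets (4.88 in 15EN, 4.87 in VC) and the labelling controls (6.24 and 6.49) lay within the range of the negative controls. At that level they can show little of a difference. The negative controls were 0.22 higher in VC, also with no overlap, the labelling controls 0.25 higher in VC with overlapping ranges, the ERCC probe sets differed by 0.008, and the positive controls were 0.20 higher in 15EN. Directions after scaling to the hybridization controls rest on those 4 probe sets alone.

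The first pattern weighed is the count of changed genes. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes, the real one with 3787, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached. The splits that, as the real one does, parted all 3 same-numbered pairs also gave 0 genes apart from the real one. The compound, which the design names, stays open as an untested explanation.

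The next pattern is the place of 15EN replicate 3 between the other 15EN arrays and the VC arrays. Vehicle RNA mixed into the array would give equal shares from both directions if the deposited values were plain log2 signal. The genes that rose in the other 2 arrays gave a vehicle share of 53.1% (51.1 to 55.0). The genes that fell gave 17.5% (15.9 to 19.3), and the intervals resample genes within 1 array. The normalization is not stated, and on a stretched log2 scale a mixture would give unequal shares too. These shares thus cannot decide on mixed vehicle RNA, which stays open. A weaker response of the same kind would scale each gene list alike, and it stays open: with an error of each array taken from the VC arrays, 2 of the 11 called lists, histones (share 0.409) and p53 targets (0.797), left out the pooled share of 0.677. More substrate-adherent or matrix-producing cells may contribute. Against 15EN replicates 1 and 2 the substrate-adherent list lay at 0.40, the 99.91 percentile of 10000 brightness-matched random lists. The matrix list lay at 0.55, and the glial list at the 54.6 percentile. These percentiles compare genes and do not measure the spread between arrays. The substrate-adherent median relative to the VC mean was -0.21, 0.13 and 0.16 in 15EN replicates 1, 2 and 3. It was -0.23, 0.16 and 0.04 in the VC replicates, so replicate 3 lay close to 15EN replicate 2 and within the VC range. Of the 4 brightest members of the substrate-adherent list, ITGB1, VIM and NOTCH2 (14.79, 14.92 and 13.35 in 15EN replicate 3) stayed below their VC means (16.16, 15.68 and 14.49). ANXA2 (15.81) lay above its own (15.67), so a partial return toward vehicle, a change within the same cells or the passage of that array stays open.

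The last pattern is the shift of the 11 called lists. A shift that depends on probe set brightness would leave list medians within the central 95% of random lists matched on brightness, and 0 of 11 lay there. A shift that depends on the genomic length of the gene would leave them within that range of lists matched on length and brightness, and 1 of 11 lay there (oxidative phosphorylation, median 0.38 in a range of -0.03 to 0.41). Length is thus open for that list, as is brightness, since its call was lost after removal of a brightness trend (median 0.24, adjusted p = 0.0825), while for the other 10 these trends were not the whole of the shift. A single offset per array, such as the difference in hybridization controls, moves all genes alike, so the size of a list's difference from other genes stays the same. Camera's p can still move with it. Scaling to the hybridization controls kept 10 of the 11 calls, lost that of the interferon list (adjusted p = 0.0967) and gained that of the vesicle list (0.0494). Quantile normalization kept 10 of the 11 calls, and a response to the compound stays an untested hypothesis, with other steps of the unstated normalization open.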

How the results depend on the processing

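Scaling by the hybridization controls and removal of a brightness trend were chosen after the data were seen, and all other settings here before. With the replicate number as a block, 2415 genes were higher and 1788 lower, with 3707 of the 4203 shared with the unblocked fit. The 11 lists kept their calls, and apart from PNMT and GABRR2 it changed no other call of a named gene or list. The fry test called 9 lists, 5 of them also by camera and the rest dopamine synthesis (adjusted p = 0.00509), unfolded protein and integrated stress response (0.00833), synaptic vesicles (0.0252) and NRF2 targets (0.0252). With the block, which leaves fewer degrees of freedom, fry called 0 lists. Its lowest adjusted p of 0.0647 was shared by several lists, p53 targets among them. Camera with an estimated correlation also called 0. Leaving out arrays gave 526 to 3227 higher and 495 to 2240 lower genes, the lowest without both arrays of replicate 2, with fewer samples in each fit and 0 genes in opposite directions. The unmoderated least squares fit gave 789 higher and 637 lower genes, with fewer degrees of freedom, and 1.5-fold instead of 2-fold gave 2945 and 2185. Scaling by the hybridization controls gave 12150 higher and 437 lower genes, and 7090 and 276 at 2-fold, because it adds 0.87 to every difference, and it turned IFI44 (0.0198), OAS1 (0.14), TH (0.78) and SLC18A2 (0.85) positive, all below the median gene of 0.88. Other settings kept the counts within 1.5 times. Of 1449 values for the named genes, which leave out array weights, the other prior and the unmoderated fit, 79 fell below the threshold, 14 rose past it and 4 reversed; 58 of 91 genes stayed on their side in these. For the 11 called and 5 dopamine, GABA and vesicle lists, 9 of 272 values from camera with the preset correlation lost and 4 gained a call, 0 reversed in camera's direction, and 12 of 16 lists stayed on their side. With an estimated correlation all 11 lost their calls. For the neuronal cytoskeleton list that estimate was 0.011, close to the preset 0.01, yet camera's adjusted p went from 8.16e-07 to 0.238. The vesicle list, at 0.008, went from 0.0535 to 0.418. A higher correlation between members thus does not account for the change in these lists. The other called lists had estimates of 0.058 to 0.607. What else differs between the 2 camera settings, and the cause of the other list calls lost, was not tested. Signals near the negative controls limit what can be said of TH, DDC, SLC18A2, SLC6A3, ABAT, PNMT, GABRR2, GABRA4, GFRA3, OAS1, OAS3, IFI44 and ATP5F1D in both groups, of DBH, ADCY1, NLGN2, COL4A1, COL5A1, INSIG1, SQLE and COX4I1 in 15EN, and of NDUFA6 and YAP1 in VC.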

Other observations

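All gene families here, and the genes named with them, were chosen after their values were seen, so the adjusted p given (camera over the 10 families) describes them and tests nothing new. Circadian clock genes rose, 12 higher and 0 lower of 18, with a median of 1.39 (adjusted p = 2.12e-08, and adjusted p = 0.153 with an estimated correlation). Examples were the repressor NR1D1 (4.15 ± 0.54) and its relative NR1D2 (1.82 ± 0.22), CIART (3.24 ± 0.36), the period genes PER2 (3.09 ± 0.70) and PER3 (1.88 ± 0.26) and the cryptochrome CRY1 (1.78 ± 0.25), as well as the activators BMAL1 (1.20 ± 0.21) and RORA (2.78 ± 0.43). CIART, PER2 and CRY1 lay within the range of the negative controls in VC, so the sizes of their rises are uncertain. Mitochondrial ribosomal protein genes rose with a median of 0.79, 41 higher and 0 lower of 74 (adjusted p = 3.9e-13, and adjusted p = 0.00659 with an estimated correlation). Examples were MRPS18B (2.69 ± 0.21), MRPL49 (2.09 ± 0.28) and MRPL58 (2.04 ± 0.23, dim in VC), beside the cytosolic ribosomal proteins with 1 higher and 3 lower of 44. Zinc finger genes with ZNF symbols had a median of 0.44, 135 higher and 15 lower of 492 (adjusted p = 5.81e-08, and adjusted p = 0.314 with an estimated correlation), with 219 higher without 15EN replicate 3. Genes whose symbols start with MED (Mediator, 10 higher, 0 lower of 26), EIF (mostly initiation factors, 16 and 4 of 49) and PSM (proteasome, 17 and 3 of 49) had medians of 0.51, 0.47 and 0.46 (adjusted p = 0.000411, 0.000742 and 0.00014, and adjusted p = 0.195, 0.287 and 0.153 with an estimated correlation). The 4 lower EIF genes were the kinase gene EIF2AK2, the repressor genes EIF4EBP1 and EIF4EBP2, and EIF4E3.

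Protocadherin genes of the beta cluster, adhesion proteins of neurons, fell in 14 of 16 cases with 0 higher and a median of -1.62, or -0.76 after scaling to the hybridization controls (adjusted p = 7.25e-12, and adjusted p = 0.1 with an estimated correlation). Examples were PCDHB6 (-3.71 ± 0.23) and PCDHB14 (-2.90 ± 0.33). Sizes per gene are uncertain, because these paralogs are near-identical and several, such as PCDHB5 (5.28), lay within the range of the negative controls in 15EN. Tubulin genes had 1 higher and 9 lower of 18 with a median of -0.78, which was 0.09 after that scaling (adjusted p = 1.95e-05, and adjusted p = 0.125 with an estimated correlation). TUBB fell by 2.44 ± 0.21, TUBA1A by 1.66 ± 0.21 and TUBA1C by 1.36 ± 0.20, whereas TUBA4A, dim in VC, rose by 1.06 ± 0.29. Kinesins (1 higher, 10 lower of 43) and collagens (0 and 11 of 42) had medians of -0.30 and -0.19 that turned to 0.57 and 0.68 after that scaling (adjusted p = 0.000411 and 0.000577, and adjusted p = 0.1 and 0.322 with an estimated correlation). Without 15EN replicate 3 the counts were 4 higher and 14 lower for kinesins and 1 and 15 for collagens. Within the list of unfolded protein and integrated stress response, members of several kinds moved in either direction. ATF4 (2.27), DDIT3 (2.78), ERN1 (1.35), XBP1 (0.78) and the co-chaperone gene DNAJB9 (1.32) rose, while PHGDH (-1.71), DDIT4 (-1.36) and the chaperone genes HSPA5 (-1.10) and PDIA4 (-2.84) fell, all past adjusted p 0.05, and no part of the list was tested alone. DDIT3 was dim in VC. Among NRF2 targets, GCLM (2.27), OSGIN1 (2.82), NQO1 (1.93) and TXNRD1 (1.71) rose beside HMOX1, and AKR1C3 (-1.60), AKR1C1 (-1.38) and CAT (-1.09) fell. OSGIN1 and HMOX1 were dim in VC, AKR1C3 in 15EN, and AKR1C1 and CAT in both groups. In genes at or above the median signal, 22.6% of those up to 10 kb long rose and 9.92% fell, against 14.1% and 22.0% of those over 200 kb.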
